A study of Mus musculus with 21 samples.

How the data were processed

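The cells were A2lox-Sox7-Myc mouse embryonic stem cells, a line derived from E14Tg2a that makes a Myc-tagged Sox7 protein when doxycycline is added. They were differentiated as embryoid bodies (EBs), floating aggregates in which mesoderm forms, and collected at day 4. Per the labels, doxycycline was given at 1 µg/ml for 24 h in the ChIP-seq and ATAC-seq samples. ChIP-seq with an anti-Myc antibody was done on unsorted cells, with 4 uninduced and 4 induced samples and 1 input sample. ATAC-seq was done on cells sorted as PDGFRα+FLK1+, here called CPC (cardiac progenitors in the series' design text), and as PDGFRα−FLK1+, here called EPC (endothelial progenitors), with 2 uninduced and 2 induced samples of each. The growth protocol also names a PDGFRα+FLK1− sort, which differs from the characteristics of the ATAC samples, and groups were taken from the characteristics. The 4 RNA-seq samples, with 12 h of doxycycline, were not analysed here.

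The deposited files were peak lists, 1 per library, and 4 lists that the authors derived from them. Per the submitters' processing notes, reads were placed on GRCm38 (mm10), and the tools named there with no role include Bowtie2, SAMtools, bedtools, MACS 1.4 and Trimmomatic. Each peak carries a score as deposited by the authors' peak caller, which in the MACS 1.4 format is minus 10 times the log10 of the peak's p-value. That score is each peak's own value and was used to rank or filter peaks within a list. Its mean over the libraries with a peak also ranked merged regions, only to choose which to name; as scores depend on depth, which is unknown, that order carries no weight in any test. No list holds read counts, so the depth of each library is unknown, and a peak that is missing from a list can mean a shallower library as well as a closed or unbound site. The lowest score was about 40 in the input list and in all ChIP lists except uninduced list 4, where it was 50.1, and about 50 in the ATAC lists.

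Lists of the same assay were compared before use. Uninduced ChIP lists 2 and 4 shared 585 of the 772 peak starts of the shorter list (75.8%), and 448 peaks had the same start and end, of which 327 had scores within 1 of each other. Among the other 35 pairs of ChIP and input lists, the highest share of equal starts was 1.04%. Uninduced lists 2 and 4 therefore differed by less than any other pair and were counted as 1 library, with their mean for values per library and a peak in either list counted as present. The planned comparison of 4 against 4 thereby became 4 induced against 3 uninduced libraries, a change made after the data were examined, and the values for 4 uninduced lists stand in the closing section.

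Peaks of an assay were merged into regions where they overlapped by 1 bp or more, giving 4548 ChIP regions and 51264 ATAC regions. An induced ChIP site was a region with a peak in at least 3 of 4 induced libraries and in 0 uninduced libraries, and an uninduced-only site was a region with a peak in all 3 uninduced and 0 induced libraries. A gained ATAC region had a peak in both induced and neither uninduced library of a cell type, and a lost region the reverse. CPC-only and EPC-only regions had a peak in all 4 libraries of the cell type and in 0 of the other. Because each of these is a call of presence, the counts were set beside the same counts for the other ways of splitting the libraries.

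Genes came from a RefSeq table of GRCm38.p6 with 21887 protein-coding genes on 21 chromosomes. The table has no strand, so the planned rule of the nearest transcription start site was replaced: a region was assigned to every protein-coding gene whose body it overlapped, and otherwise to the nearest gene within 50 kb. A region said to lie inside a gene overlaps its body by 1 bp or more, and distances run to the nearer gene boundary. Exons and introns were not used here. As a check of the build, 26.7% of ATAC regions lay within 1 kb of a gene boundary, against 7.47% after a shift of 100 kb.

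Values per library were compared with two-sided exact permutation tests, in which the smaller tail is doubled. The smallest p is 0.0571 for 4 against 3 libraries and 0.333 for 2 against 2, so neither comparison can pass 0.05. The 4 ChIP measures were adjusted together by the Benjamini-Hochberg method. Overlaps between region sets were tested with two-sided Fisher's exact tests across regions, which are not independent replicates, so these p-values describe the lists and not the cultures. Shares of regions have exact (Clopper-Pearson) 95% intervals, which cover counting error only. All 326 members of the 14 gene lists matched the gene table. For each list and each of 7 region sets, the number of members with a region of the set was compared with 10000 random lists matched on the number of regions per gene, with Benjamini-Hochberg adjustment over all 98 tests. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

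The named genes followed a rule: the genes of the 10 regions with the highest mean score in the induced ChIP, gained and lost sets, list members with a region of the set (at most 8 per list), and Sox7 in every library. ChIP regions that overlap an input peak were passed over. Genes of CPC-only and EPC-only regions, and of the authors' own lists, are list members outside that rule and were chosen after their values were seen. The groups, tests, gene lists, this rule and most alternatives were fixed before the data were examined. The alternatives were stricter scores, another merging rule, lists of equal length, other numbers of required libraries, a replicate block, other gene distances and leaving out each library. The planned motif tests were not run, because no genome sequence was used here.

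On simulated libraries with 200 changed regions, the rule for induced ChIP sites recovered 93.5% of them and called 58 other regions among 4548. The rule for gained regions recovered 78.5% in CPC and 81.5% in EPC, and called 1247 and 1270 other regions among 51264. Apart from the changed regions, each simulated library was drawn at the same rate per region, so differences in list length between the real libraries were not kept. That rate was the mean over all libraries of the assay, so differences between groups and agreement between replicates were not kept either. Random gene lists gave p under 0.05 in 4.67% of 300 cases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.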

Results

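Sox7, a transcription factor of the SOXF group that acts in endothelial and endodermal cells, was induced in differentiating mouse embryonic stem cells, and the series asked where it binds and how it changes chromatin accessibility in cardiovascular progenitors. Anti-Myc ChIP-seq gave 8 peak lists (4 uninduced, 4 induced) and 1 input list. ATAC-seq, which maps open chromatin by transposase insertion, gave 8 lists, 2 for each of uninduced and induced CPC (PDGFRα+FLK1+) and EPC (PDGFRα−FLK1+). The lists held 772 to 2807 ChIP peaks, 689 input peaks and 23068 to 30732 ATAC peaks, and the sequencing depth behind them is unknown. All positions are on GRCm38.

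At the Sox7 gene itself (chromosome 14, 63943706 to 63950732), an ATAC peak inside the gene body was called in 4 of 4 induced libraries and in 0 of 4 uninduced libraries. The merged region spanned 63947488 to 63948950 and was present in both CPC and both EPC induced libraries. The anti-Myc ChIP lists had a peak there in induced replicate 3 alone. Whether the ATAC peak inside the gene came from the gene or from DNA of the induced Sox7 transgene cannot be told. The same limit holds wherever this region is counted as gained below. A second ATAC peak, at the lower boundary of the gene, was called in all 4 EPC libraries, both induced CPC libraries and 1 of 2 uninduced CPC libraries. Another, at 63957438 to 63958592 and 6.71 kb outside the gene, was called in 4 of 4 EPC libraries and 0 of 4 CPC libraries.

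**Figure D1:**
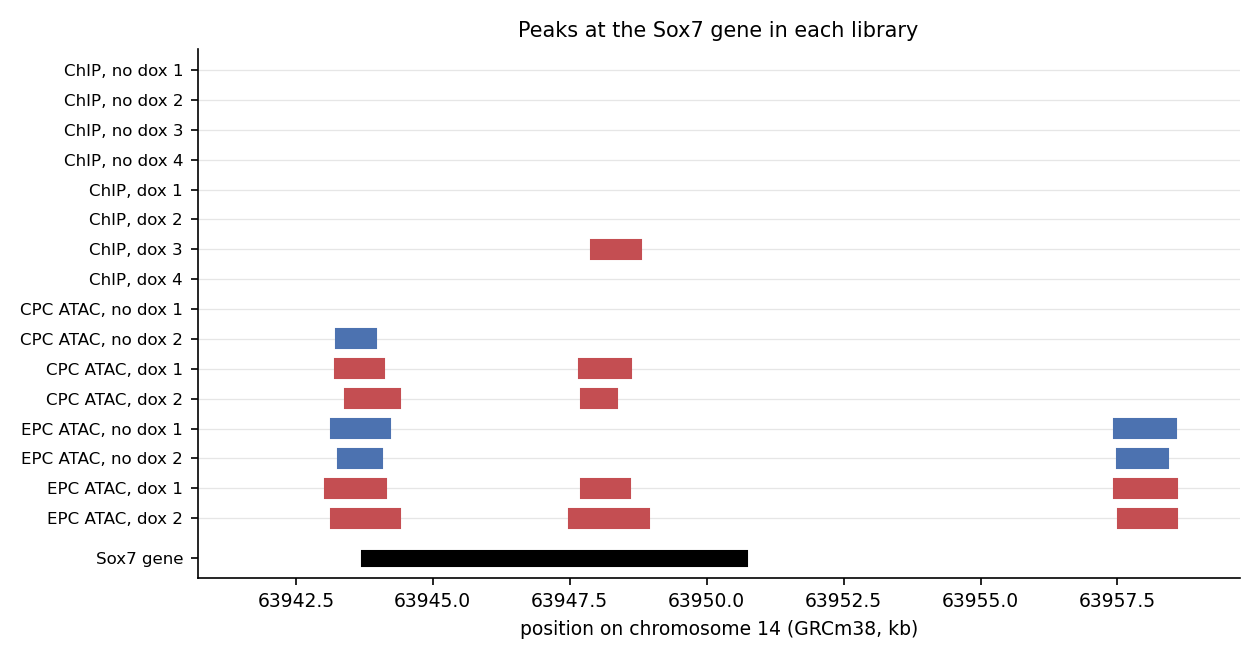
Peaks at the Sox7 gene in each ChIP and ATAC library, with position on chromosome 14 in kb on the horizontal axis, uninduced libraries in blue, induced libraries in red and the gene body in black. The peak inside the gene is in 4 of 4 induced and 0 of 4 uninduced ATAC libraries, and the peak on the right is in 4 of 4 EPC and 0 of 4 CPC libraries.

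The first comparison asked where Myc-tagged Sox7 was found on the genome after induction. There were 235 induced sites, of which 95 had a peak in all 4 induced libraries and 140 in 3 of them, against 2 sites seen in uninduced libraries alone. By mean peak score, the leading sites lay 38.8 kb from Fth1, the ferritin heavy chain gene (chromosome 19, 9940552 to 9941778), 16.3 kb from Slc38a11, inside Tead1, a transcription factor of the Hippo pathway (chromosome 7, 112823135 to 112824320), 9.87 kb from the collagen gene Col6a3, 22.3 kb from Lmo1, and inside Fam155a and Ankrd29. The other 3 of the 10 leading sites had no protein-coding gene within 50 kb. Among endothelial genes, sites lay inside Vwf, which encodes von Willebrand factor (chromosome 6, 125552392 to 125553442), and at 2 positions inside Ets1 (chromosome 9, 32692100 to 32693087 and 32715774 to 32716839). Sites also lay inside Notch4 (chromosome 17, 34586275 to 34587419), inside the SOX genes Sox5 and Sox13, and inside Pax7.

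Of the endoderm genes, 4 had an induced site, among them Ttr and Col4a1, with sites inside the gene (chromosome 18, 20672849 to 20673853, and chromosome 8, 11308250 to 11309429), and Lamb1, with a site 42.8 kb away. This was 4 of 23 endoderm genes with any region, where matched random lists gave 0.687, and it did not pass the adjustment (permutation p = 0.0082, adjusted p = 0.301). The endothelial list had 2 of 29 genes (0.971 expected), the SOX list 2 of 19 (0.42 expected), and the blood, cardiac, early mesoderm, Wnt pathway and BMP and TGF-beta pathway, smooth muscle and housekeeping lists had 0. The pluripotency (Dnmt3b), neural (Pax7), Notch pathway (Notch4) and VEGF and guidance (Spry2) lists had 1 each. No list passed for induced ChIP sites, and over all 98 tests of lists and region sets 1 passed after adjustment and 5 before it.

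Induced libraries held 1808 ± 741 peaks (SD, n = 4) and uninduced libraries 960.5 ± 87.1 (SD, n = 3), a ratio of 1.88. The share of peaks on an input peak was 32.9% ± 12.5 in induced and 54.4% ± 3.63 in uninduced libraries (SD, n = 4 and 3), although the number of such peaks was 485 to 552 in every ChIP list. All 4 measures per library gave the same adjusted exact permutation p of 0.114 (n = 4 and 3), including covered length (2249580 against 1431160 bp) and median peak width (983 against 1066 bp), so none passed. Of the 235 induced sites, 3 overlapped an input peak (1.28%, 95% interval 0.264 to 3.69), against 392 of the 478 regions found in every ChIP library (82%, 95% interval 78.3 to 85.3). The rule for induced sites leaves out regions with an uninduced peak, so this contrast follows at least in part from the definition. Regions seen in 1 induced library only had a like share, 29 of 2339 (1.24%). The number of induced sites depended on the score: 155 sites were called with a score of 50 or more in every list and 36 with a score of 100 or more, and 0 uninduced-only sites in each case. With every list reduced to its 772 highest-scoring peaks, there were 71 induced and 8 uninduced-only sites. With 1 induced library left out and 2 of the other 3 required, the induced sites numbered 440 without replicate 1, 471 without replicate 2, 289 without replicate 3 and 577 without replicate 4.

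**Figure D2:**
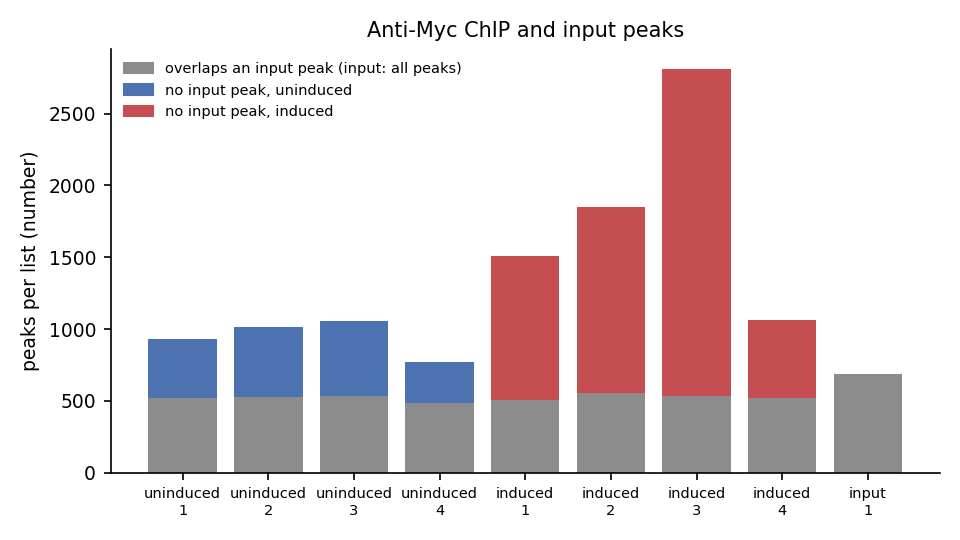
Number of peaks in each anti-Myc ChIP list and in the input list, with peaks that overlap an input peak in grey and the others in blue (uninduced) or red (induced). Induced lists held 1061 to 2807 peaks and uninduced lists 772 to 1059, where uninduced lists 2 and 4 were counted as 1 library in all tests.

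The second comparison asked how induction changed open chromatin in CPC. In CPC, 2946 regions were gained and 1203 lost. The gained region with the highest mean score lay 12.6 kb from Zscan4c (chromosome 7, 10991688 to 10993134), and the next 12.7 kb from Zscan4f, genes of a cluster of near-identical copies. Other leading gained regions lay 4 kb from Ccne1, which encodes cyclin E1, inside Vangl2, a planar cell polarity gene, 21.6 kb from Ssbp2, 11.5 kb from Npffr2 and inside Tafa2. Leading lost regions lay inside Septin11, Medag, Nme9, Actg2 and Sybu, and the other 5 of the 10 had no protein-coding gene within 50 kb.

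Gained CPC regions were assigned to 9 of 29 endothelial genes (7.9 expected), among them Tek, Flt1, Erg, Ets1, Cdh5, Nrp2, S1pr1 and Sox17. They were assigned to 8 of 25 cardiac genes (6.18 expected), including Isl1, Tbx20, Hand2 and Tnni1, and to 9 of 23 endoderm genes (4.87 expected), including Foxa2, Sox17 and Dab2. None of these 3 lists passed, with permutation p = 0.0528 and adjusted p = 0.862 for endoderm. Lost CPC regions were assigned to Gata4 and Smarcd3 of the cardiac list (2.85 expected), S1pr1 of the endothelial list (3.7 expected) and Eomes of the early mesoderm list (1.63 expected), and no list passed.

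In EPC, 3139 regions were gained and 935 lost. The leading gained regions lay inside Tiam1 (chromosome 16, 89862862 to 89864065), an activator of the GTPase Rac, inside Tmem132d, Nav2, Rell1, Dock2 and Agbl4, 41.6 kb from Adamts18, 23.6 kb from Peg10, 18.7 kb from Rasd2 and 19.7 kb from Spty2d1. Leading lost regions lay 23.2 kb from the apelin receptor gene Aplnr, 2.24 kb from Ino80c, inside Cdkal1 and Spns2, and near Fer, Xirp2 and Sim2.

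Gained EPC regions were assigned to 10 of 29 endothelial genes (8.65 expected), including Aplnr, Flt4, S1pr1, Ets1, Erg and Tek, and to 9 of 23 endoderm genes (5.22 expected), including Ttr, Lamc1, Lamb1 and Foxa2. They were assigned to 7 of 19 SOX genes (3.75 expected: Sox1, Sox5, Sox6, Sox7, Sox11, Sox13 and Sox15) and to 0 of 21 blood genes (3.35 expected). The blood list had the lowest p of the gained EPC sets and did not pass (permutation p = 0.0382, adjusted p = 0.749). Lost EPC regions were assigned to 5 of 25 cardiac genes (2.39 expected: Gata4, Hand1, Mef2c, Myl7 and Actc1) and to 4 of 29 endothelial genes (3.16 expected: Aplnr, Fli1, Flt1 and Cdh5), and no list passed.

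Peak numbers were 28635 ± 928 in induced and 25304 ± 3162 in uninduced CPC, and 29824 ± 1285 in induced and 25814 ± 2998 in uninduced EPC (SD, n = 2 each), with exact permutation p = 0.333 in each cell type, the smallest that 2 against 2 allows. The highest count among the other splits of the 4 libraries was 1123 in CPC and 1093 in EPC, so gained regions were 2.62 and 2.87 times as many, while lost regions were 1203 and 935. On simulated libraries with 200 changed regions, the same rule also called 1247 unchanged regions in CPC and 1270 in EPC. Those libraries were drawn at a mean rate per region over all ATAC libraries, without agreement between replicates or differences between cell types. Their counts therefore cannot give the number of false calls in the real lists. The balance of gains and losses depended on list length: with each library reduced to its 23068 highest-scoring peaks, there were 1918 gained and 1536 lost regions in CPC and 1893 gained and 1303 lost in EPC. Without uninduced replicate 2, the shortest list of each cell type, losses outnumbered gains (4535 against 3707 in CPC and 4035 against 3894 in EPC). Leaving out any other library, which relaxes the rule, gave 5279 to 6439 gained and 1895 to 2633 lost regions in CPC, and 5565 to 7083 gained and 1634 to 2357 lost in EPC.

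**Figure D3:**
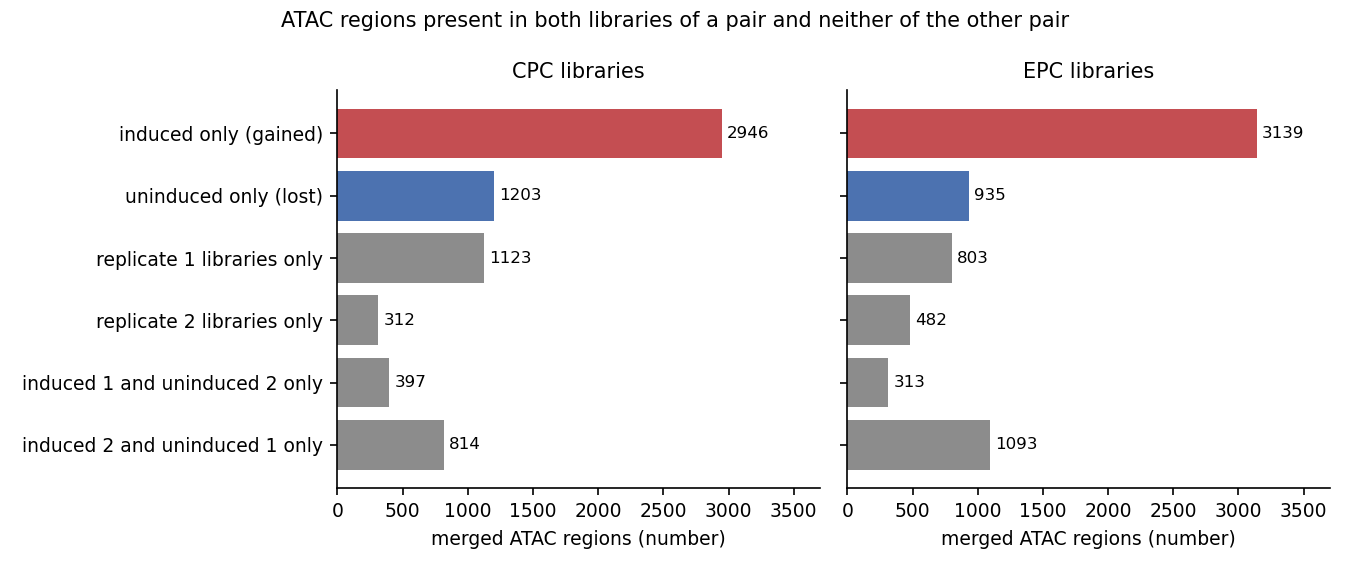
Merged ATAC regions with a peak in both libraries of a pair and in neither of the other pair, for CPC (left) and EPC (right), with gained regions in red, lost regions in blue and the other splits of the same 4 libraries in grey. Gained regions number 2946 in CPC and 3139 in EPC, and the highest grey bars are 1123 and 1093.

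Gained regions were shared between the cell types, which have separate uninduced libraries. There were 593 regions gained in both, where independent lists would share 180 (odds ratio 4.53, 95% interval 4.1 to 5, Fisher's exact p = 1.26e-157 across 51264 regions). That background holds regions with an uninduced peak, which cannot be gained. Among the 12101 regions with no uninduced ATAC peak, a background chosen after the data were examined, 593 were shared and 386 expected (odds ratio 2.03, 95% interval 1.81 to 2.26, Fisher's exact p = 8.86e-35). Over all regions, leaving out 1 library gave odds ratios of 2.58 (without induced EPC replicate 1) to 4.1, and of 2.8 and 2.92 without induced CPC replicates 1 and 2, 2.96 without uninduced CPC replicate 1 and 2.82 without induced EPC replicate 2. These included regions inside Sox7, Flt1, Erg, Ets1, Sox5 and Isl1, 2 regions near Foxa2, and 1 region 12.7 kb from Tek, the gene of the angiopoietin receptor. Lost regions shared 31, where 21.9 were expected over all regions (odds ratio 1.44, 95% interval 0.967 to 2.07, Fisher's exact p = 0.0623). Regions gained in CPC and lost in EPC numbered 11, and regions lost in CPC and gained in EPC 13.

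The third comparison asked how open chromatin differed between CPC and EPC whatever the doxycycline state. There were 1077 EPC-only regions and 922 CPC-only regions. EPC-only regions were assigned to 8 of 21 blood genes, where 1.3 were expected (permutation p = 0.0002, the smallest that 10000 random lists can give, adjusted p = 0.0196). These were the haematopoietic transcriptional regulator genes Tal1, Gata1, Gata2, Spi1, Ikzf1 and Cbfa2t3, and Itga2b and Ptprc, which encode the surface proteins CD41 and CD45. With genes assigned only within 10 kb, 6 blood genes had an EPC-only region and the list no longer passed (permutation test, adjusted p = 0.0588, against 0.0196 to 0.0392 under the other settings).

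EPC-only regions were also assigned to 9 of 29 endothelial genes (Cdh5, Flt1, Egfl7, Robo4, Erg, Fli1, Ets1, Icam2 and Cd34), where 3.55 were expected, and this did not pass (permutation p = 0.0092, adjusted p = 0.301). One of them lay inside Flt1, a VEGF receptor gene (chromosome 5, 147657355 to 147658748), and was among the 10 EPC-only regions with the highest mean score. CPC-only regions were assigned to 6 of 25 cardiac genes (Tbx20, Hand2, Ryr2, Smyd1, Fgf10 and Wnt2), where 2.16 were expected, and this did not pass either (permutation p = 0.027, adjusted p = 0.661). Of CPC-only regions, 4.01% lay within 1 kb of a gene boundary, and of EPC-only regions 8.17%, against 27.1% of all other ATAC regions in each case (odds ratios 0.112 and 0.239, Fisher's exact adjusted p = 1.35e-75 and 4.1e-54).

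The last comparison asked whether Sox7 sites fell where accessibility appeared. At the 235 induced ChIP sites, an ATAC peak was present at 32.6% ± 4.51 of sites in uninduced and 69.6% ± 2.11 in induced CPC, and at 47% ± 5.72 in uninduced and 77.2% ± 0.903 in induced EPC (SD, n = 2 each). In single libraries these shares ran from 29.4% (95% interval 23.6 to 35.6) in an uninduced CPC library to 77.9% (95% interval 72 to 83) in an induced EPC library. The 478 regions found in every ChIP library had ATAC peaks at 72.4% ± 2.66 and 70.5% ± 0.888 in uninduced and induced CPC, and 73.8% ± 0.888 and 70.4% ± 3.11 in EPC (SD, n = 2 each). Of these regions, 392 (82%) lay on an input peak, so they are mostly background and no matched control for the induced sites. For the induced sites the mean difference over both cell types was 33.6 percentage points, with an exact permutation p of 0.0556 for relabelling within cell type, the smallest that design allows.

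Gained CPC regions overlapped an induced Sox7 site in 63 of 2946 cases (2.14%), against 0.308% of all other ATAC regions (odds ratio 7.06, 95% interval 5.16 to 9.57, Fisher's exact p = 4.75e-28). Gained EPC regions did so in 48 of 3139 cases (1.53%), against 0.341% (odds ratio 4.54, 95% interval 3.21 to 6.31, Fisher's exact p = 2.27e-15). The odds ratio moved by over 1.5 times without an induced ATAC library, to 4.11 and 4.25 in CPC without replicates 1 and 2, and to 2.48 and 2.96 in EPC without replicates 1 and 2. Among regions with no uninduced peak in the cell type it was 7.08 in CPC and 7.7 in EPC, and with presence at a score of 100 and any peak ruling out absence 15.3 and 9.33, settings chosen after the data were examined. No lost region overlapped an induced site, in 1203 lost CPC regions (Fisher's exact p = 0.0110) and 935 lost EPC regions (Fisher's exact p = 0.0365). The absence was not particular to lost regions, since 0 of 922 CPC-only regions overlapped one either (Fisher's exact p = 0.0363), and the reference in these tests includes the gained regions. Of 1077 EPC-only regions, 4 did (0.371%, against 0.414% of all other ATAC regions, odds ratio 0.896). Of the 235 sites, 22 lay in regions gained in both cell types, including those inside Sox5, Sox13, Dock2 and Ptpre and one near Peg10, 41 in regions gained in CPC alone and 26 in EPC alone, a count chosen after the data were examined. An ATAC peak was already present in an uninduced library at 92 sites in CPC and 128 in EPC, which cannot be gained, so these counts do not compare the cell types. Sites inside Vwf and Notch4 had an ATAC peak in all 8 libraries, while the sites inside Pax7 and near Lamb1 had one in none. Against regions open in all 4 libraries of the cell type, the odds ratios were 5.56 (95% interval 3.86 to 8.02) in CPC and 2.78 (95% interval 1.92 to 3.98) in EPC. That comparison leaves out sites with a peak in uninduced ChIP. With these kept, a check chosen after the data were examined, 422 sites away from input peaks gave odds ratios of 2.32 (95% interval 1.71 to 3.12) and 1.43 (95% interval 1.02 to 1.97).

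**Figure D4:**
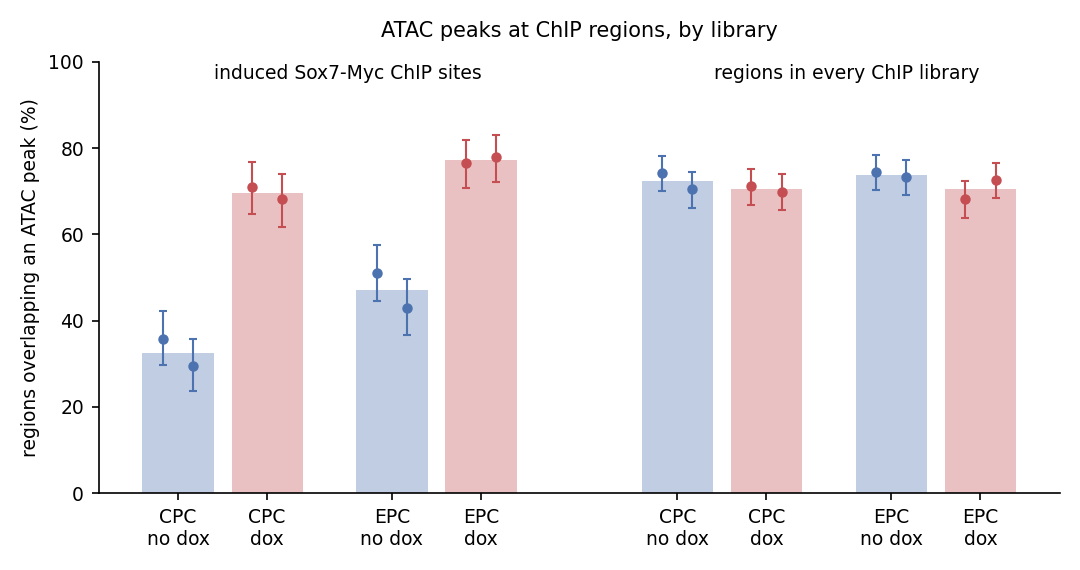
Percent of ChIP regions that overlap an ATAC peak in each library, for the 235 induced sites (left) and the 478 regions found in every ChIP library (right). Of the 478 regions, 392 overlap an input peak, so they are no matched control. Bars are means of 2 libraries, points are libraries and error bars are exact 95% binomial intervals; at induced sites the means run from 32.6% to 69.6% in CPC and from 47% to 77.2% in EPC.

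The lists the authors derived were set beside these sets. The authors' deposited Sox7 list held 666 regions, of which 404 overlapped a peak in 2 induced lists, 161 in 3 and 101 in 4, and 93 (14%) overlapped a peak in an uninduced list. By list, 29, 29 and 42 regions overlapped uninduced lists 1, 2 and 3, and 0 overlapped uninduced list 4 or the input list. The Sox7 list overlapped 232 of the 235 induced sites. The authors' deposited lists of induced-only ATAC regions held 3093 regions in CPC and 3267 in EPC, and the overlap of the 2 induced lists without any region touching an uninduced peak gave the same 3093 and 3267 regions. The remaining list, named for Sox7 and Gata4, held 117 regions, all within the Sox7 list; the source of its Gata4 sites is not given in the sources used here. Of the Sox7 list's own regions, 117 overlapped it. In uninduced CPC, 68.4% and 60.7% of these Sox7 list regions had an ATAC peak, against 21.5% and 18.2% of the other 549, and in uninduced EPC 76.1% and 66.7%, against 34.6% and 26.6%. In each of the 8 ATAC libraries the odds ratio was 5.5 or higher, with adjusted Fisher's exact p of 1.38e-11 or lower. Their share in gained regions was lower than that of the other 549, at 13.7% against 19.9% in CPC (odds ratio 0.64, adjusted Fisher's exact p = 0.151) and 6.84% against 18.8% in EPC (odds ratio 0.318, adjusted Fisher's exact p = 0.00108). A region with an uninduced peak cannot be gained, so these lower shares follow at least in part from the peaks in uninduced libraries. Whether a difference remains among regions without such a peak was not tested. These tests of the Sox7 and Gata4 list were chosen after the data were examined.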

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

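Counting uninduced lists 2 and 4 as 2 libraries was the planned comparison, and counting them as 1, as in the main values, was chosen after seeing the data. The other settings chosen after seeing the data were a score of 50 in every ChIP list, the p from absolute differences, the authors' rule for gained regions, gene boundaries and equal list lengths for the gene lists, all settings for the share of sites with an ATAC peak, equal lengths of ATAC lists, ChIP lists or both and strict presence for the Sox7 site odds ratios, the background without uninduced peaks for these and for shared gains, and leaving out libraries for the overlaps, those odds ratios and the blood list. Of 235 alternative values, 187 stayed on their side of the threshold or within 1.5 times the main count, 47 counts moved further and 1 call was lost. Many of the 187 could not change side. Tests of ChIP measures, ATAC peak numbers and shares of sites with an ATAC peak cannot pass 0.05 here, except ChIP with 4 against 4. The CPC peak number difference fell from 3331 to 1095 without uninduced replicate 2 and still counted as unchanged. The tally is therefore no measure of stability. The balance of gained and lost regions, which compares a pair of counts, turned toward losses without uninduced replicate 2 in CPC and in EPC. The odds ratio of gained regions shared by CPC and EPC stayed at 2.03 to 6.1, and those of Sox7 sites in gained regions at 4.11 to 15.3 in CPC and 2.48 to 9.33 in EPC. These ranges leave out the check in which sites with a peak in uninduced ChIP were kept. Against regions open in all 4 libraries of the cell type, it gave lower odds ratios of 2.32 in CPC and 1.43 in EPC. No ChIP measure per library passed 0.05 under any setting. Those tests cannot pass at these sample sizes before adjustment, except with 4 against 4, where the adjusted exact permutation p was 0.0571 for peak number. Induced ChIP sites numbered 36 with a score of 100, 155 with 50, 71 with equal list lengths, 653 with 2 libraries required and 95 with 4, and 289 to 577 or 251 to 252 without an induced or uninduced library, a range of 251 to 577. Sites seen in uninduced libraries alone numbered 2, and 0 with a score of 100 or of 50, 9 with lists 2 and 4 as 2 libraries, 8 with equal list lengths, 28 with 2 libraries required, and 3 to 15 without one library. A requirement of 4 libraries was not run for them, as 3 remain. Gained regions numbered 1722 in CPC and 1784 in EPC with a score of 100 in all lists (lost 597 and 419), 732 and 813 when any peak ruled out absence (lost 141 and 69), and 1918 and 1893 with equal list lengths. Without one library they numbered 3707 to 6439 in CPC and 3894 to 7083 in EPC, and lost regions 1895 to 4535 and 1634 to 4035. Fewer required libraries raise these counts by construction. In uninduced libraries alone there were 3030 CPC-only and 3139 EPC-only regions, again with fewer libraries required. Within 10 kb, 0 gene lists passed, and 6 blood genes had an EPC-only region (permutation test, adjusted p = 0.0588, against 0.0196 to 0.0392 under the other settings); the cause was not tested. Replicate numbers are shared by the groups, but the labels do not say that they pair samples, and deviations of same-numbered ChIP samples correlated at −0.0975 to 0.059. With the replicate block, 250 induced ChIP sites and 20 uninduced-only sites were called, the ATAC counts are the same by construction, and the ChIP measures had an adjusted p of 0.125, the smallest that 16 sign changes allow. The motif tests and their alternatives were not run. As depth is unknown, a region without a peak cannot be called closed or unbound.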

Other observations

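The tests of splits, of replicate differences, of the Sox7 transgene, of ChIP lists of equal length and of sites with a peak in uninduced ChIP kept were chosen after the results were seen. Among regions gained in both cell types were 2 near Foxa2, which encodes an endoderm transcription factor, and regions near Klf4, Evx1, Lfng, Efnb2, Robo1 and S1pr1. At the SOX genes, Sox5 and Sox13 each had 2 regions gained in both cell types, and at each gene 1 of them overlapped an induced Sox7 ChIP site. Gained regions lay within 1 kb of a gene boundary in 9.4% of cases in CPC and 9.53% in EPC, against 27.8% of other regions in each (odds ratios 0.27 and 0.273). Lost regions were at 9.98% and 10.8%.

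The 235 induced ChIP sites exceeded every other division of the 7 libraries into 4 and 3: the real one alone, 1 of 35, gave as many, and the highest other gave 123. This count is in 1 direction, and uninduced lists 2 and 4 were merged after the data were examined. It therefore argues against chance division of the libraries as an account of the whole count but does not exclude it. With lists of equal length the real division gave 71 and the highest other 45. For sites in uninduced libraries alone, 28 of 35 divisions gave as many as the real 2, and the highest gave 86, so nothing argues against chance there. The division by cell type was the 1 of 35 divisions of the ATAC libraries with as many as 922 CPC-only or 1077 EPC-only regions, and the highest other, 593, was the division by doxycycline.

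More regions were gained than lost on induction in CPC and EPC. Differences between replicates alone would give similar counts in the other splits, but the gained count was 2.62 times the highest of these in CPC and 2.87 times in EPC. The 4 libraries of a cell type allow too few other splits to exclude that account for gains. For losses it stays open as well, as lost EPC regions (935) were fewer than the highest other split (1093). Without uninduced replicate 2, losses exceeded gains, 4535 against 3707 in CPC and 4035 against 3894 in EPC, although that setting asks for a peak in 1 uninduced but 2 induced libraries. Longer lists in the induced libraries remain open: with lists of equal length, the ratio of gained to lost regions was 1.249 in CPC and 1.45 in EPC, down from 2.45 and 3.36, which is just under the limit set in advance in CPC and above it in EPC. An excess of opening and a difference in depth between induced and uninduced libraries cannot be told apart in CPC or in EPC, since the lists carry no counts.

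For induced Sox7 sites, which lack a peak in uninduced ChIP, longer induced lists alone do not account for the concentration in gained regions. Equal list lengths were not run with sites that have such a peak kept, so list length stays open for that wider set. The lower bound of the odds ratio was 4.41 or higher in both cell types with ATAC lists of equal length. With ChIP lists of equal length it was 5.18 in CPC and 1.69 in EPC, and with both 5.02 in CPC and 2.76 in EPC. Nor do weak peaks alone: with a score of 100 or more in all lists, the planned setting, the lower bounds were 2.45 in CPC and 2.36 in EPC. With presence at a score of 100 and any peak ruling out absence, the lower bound was 5.95 or higher. Whether ChIP signal follows open chromatin in general stays open. Gained regions against regions open in all 4 libraries gave a lower bound of 1.92. However, induced sites leave out regions with a peak in uninduced ChIP, which under that account would remove sites in always-open regions. With them kept the lower bounds were 1.71 in CPC and 1.02 in EPC, so in EPC the margin is narrow. Sites on input peaks were still left out there, and the input came from uninduced cells, so that check cannot decide it either. One hypothesis, found and tested on the same data, is that Sox7 binding may accompany the opening of part of these sites, but only 2.14% of gained CPC regions and 1.53% of gained EPC regions overlap an induced site, and ChIP came from unsorted cells.

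The ATAC peak inside Sox7 was present in 4 induced and 0 uninduced ATAC libraries. DNA of the induced Sox7 transgene may be its source, since open transgene copies would yield reads that match the gene's exons, and an effect of Sox7 on its own gene is the biological alternative. These cannot be told apart, because exon positions and the transgene sequence were not used here. The anti-Myc peak at the same place in 1 induced ChIP library leaves both open.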
